A study of Mus musculus with 6 samples.

How the data were processed

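RNA sequencing of 6 libraries from mouse pancreatic cancer cell lines was used, 3 with sgROSA and 3 with sgMSRA, each guide once in ccT1, ccT4 and ccT7. Groups and lines were taken from the sample titles, and each column was matched to its sample by the sample's description. All per-sample columns were used. The files hold 35199 genes by symbol.

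The deposited table of estimated counts gives, per the labels, kallisto estimates per gene. The submitters' processing notes name bcl2fastq 2.19, kallisto 0.44.0, sleuth, DESeq2 and the build GRCm38, with no role for sleuth and DESeq2. The annotation release is not given in the sources used here, nor are strand settings. The estimated counts are whole numbers in the deposited file, and rounding them again changed nothing. The deposited table of TPM values comes from the same kallisto quantification, per the labels; TPM is relative to all transcripts of a library and keeps no depth. Kallisto shares reads among similar transcripts by likelihood, so values of pseudogenes, paralogs and overlapping genes are uncertain.

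Symbols were matched to GENCODE's annotation of GRCm38 and, through RefSeq synonyms, to older names, with 35001 of 35199 matched. Coordinates, biotypes, transcript lengths and GC contents come from that annotation, which may differ from the one used to count. Of the 12788 tested genes 99.7% had a GC content.

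Tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr with the guide as group (minimum count 10, minimum total 15), libraries scaled by TMM, and guides compared by edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. The comparison across groups has guide as its only term, since no label states another model. The comparison within lines adds the line as a block. Fold changes are sgMSRA over sgROSA on the log2 scale, and SE is the fold change divided by the root of its F value. The libraries are paired by cell line, and the pairing showed in the counts: the deviations of both libraries of a line from their group means correlated at 0.57 in ccT1, 0.78 in ccT4 and 0.79 in ccT7, and at no more than 0.04 between lines. Subtracting group means lowers the correlations between lines by construction, so only the values within lines bear on the pairing. The common dispersion was 0.20 without and 0.059 with the line block.

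Gene lists (39, written before the data were examined, without Msra) were tested by camera with a preset correlation of 0.01, adjusted over the 37 lists with at least 5 tested members. Camera with an estimated correlation and fry were run beside it. The acinar and islet lists had 2 tested members each and were not tested; the highest TPM among them were 2.16 for Zg16 and 1.91 for Mafb. Lines were compared by an F test of both line terms in the model with line and guide. CPM are counts scaled to a common library size, from edgeR. Log2 ratios per line used log2 CPM with a prior count of 2.

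Genes were named by a rule written before the data were examined. It took Msra and Pkm; then calls across groups or, failing 10, within lines; then, as values not called changed, genes with the smallest within-line p at a mean CPM of at least 1 until 20 were named. Symbols of unnamed models, Rik clones and pseudogenes were counted but not named. In each list described, up to 4 members with the smallest within-line p were taken. Per line, the 6 genes with the largest gap above the next line were taken, and per list up to 3 members with the smallest p. Prkn, Gm44502, Rps13 and Rps13-ps1 were chosen after their values were seen.

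The methods were tested on simulated counts drawn for 12598 genes from the fitted means and dispersions, with 200 genes changed. Within lines, 44% of 2-fold and 96% of 4-fold changes were recovered, with 3 false calls among 143. Genes were drawn independently and without a trend of the guide ratio with GC content, so these shares may not carry over to the real data. Across groups 0% were recovered, since differences between lines enter the spread. A planted list of 25 genes lowered by 0.5 gave a camera p far below that of an unplanted list in both comparisons. The p of that unplanted list, not adjusted over lists, was nevertheless under 0.05 in both comparisons of the same simulated counts. At that threshold the list was a false positive of the preset test. The real lists were called at a p adjusted over lists. How often the preset test gives false positives was not measured.

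Alternatives planned before the data were examined were RLE and upper quartile scaling, no filter and a stricter filter (at least 10 counts in 3 libraries and a mean CPM of at least 1), DESeq2, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1) at a mean TPM of at least 1, limma without that filter, a transcript length offset, an adjusted p of 0.1, other set tests and leaving out each line. One alternative was added after the data were seen: an offset per library for a spline trend on GC content (6 degrees of freedom) and log length (4), fitted on genes with a mean log2 CPM above 1. All 10 splits of the libraries into 3 and 3 were refitted. Libraries were thinned to the lowest total, 27796103 counts, by binomial sampling, and 95% intervals of correlations came from 1000 resamples of genes. Python 3.11.15 and matplotlib 3.10.9 drew the figures.

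The total counts, from 27796103 to 52131378, leave little counting error for most genes. Genes with a few counts per library, such as Gm44502, are limited by depth.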

Results

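RNA was sequenced from 6 cultures of mouse pancreatic cancer cells. The cells were 3 lines, ccT1, ccT4 and ccT7, grown from primary tumours of KPC mice, a model in which mutant Kras and mutant p53 are switched on in the pancreas by Cre recombinase. Each line carried the Cas9 nuclease and was sequenced once with sgROSA, a control guide RNA, and once with sgMSRA, a guide against Msra. Msra encodes methionine sulfoxide reductase A, which reduces oxidised methionine in proteins. Each guide therefore had 3 libraries, 1 per line. The estimated counts summed to 52131378 and 45726225 in ccT1 (sgROSA, then sgMSRA), to 30079662 and 27796103 in ccT4, and to 38362718 and 30055514 in ccT7. The question was how gene expression differs between cells with the guide against Msra and cells with the control guide. No line has a second library with the same guide, so tests of single genes across groups rest on the spread between these 3 lines. Within lines they rest on what remains after line and guide are fitted, with 2 residual degrees of freedom. The set test camera with a preset correlation weighs the members of a list against the other genes. Its p does not measure the spread between lines.

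The targeted gene was examined first. Msra (ENSMUSG00000054733.9; GRCm38 chromosome 14, 64122625 to 64455903, minus strand) was expressed at 4.64 ± 1.84 TPM (SD, n = 3) with sgROSA and at 3.55 ± 0.59 TPM (SD, n = 3) with sgMSRA. In ccT1 it measured 4.76 TPM with sgROSA and 4.10 TPM with sgMSRA. On the scale of log2 CPM (counts scaled to library size) the ratio in ccT1 was 0.021. In ccT4 the values were 6.42 and 3.62 TPM, and in ccT7 they were 2.73 and 2.94 TPM. The log2 fold change was −0.42 ± 0.49 (SE) across groups and −0.31 ± 0.33 (SE) within lines, with an adjusted p of 1 in edgeR's quasi-likelihood test for the latter. Without ccT4 the value was 0.076 across groups and 0.093 within lines; without ccT1 it was −0.67 and −0.51, and without ccT7 −0.58 and −0.53. Msra mRNA thus differed between the guides by less than its error, and the labels give no cut site. An insertion or deletion made by Cas9 can inactivate a protein without lowering its mRNA, so these values neither check nor contradict the labels. Pkm (chromosome 9, 59656368 to 59679375), which encodes the pyruvate kinase named in the series title, was among the abundant transcripts, at 2559 ± 149 TPM with sgROSA and 2434 ± 532 TPM with sgMSRA (SD, n = 3). Its within-line log2 fold change was −0.05 ± 0.24 (SE), with −0.30 without ccT1 and 0.22 without ccT4. The Pkm value is a total for the gene and does not separate its isoforms.

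**Figure D1:**
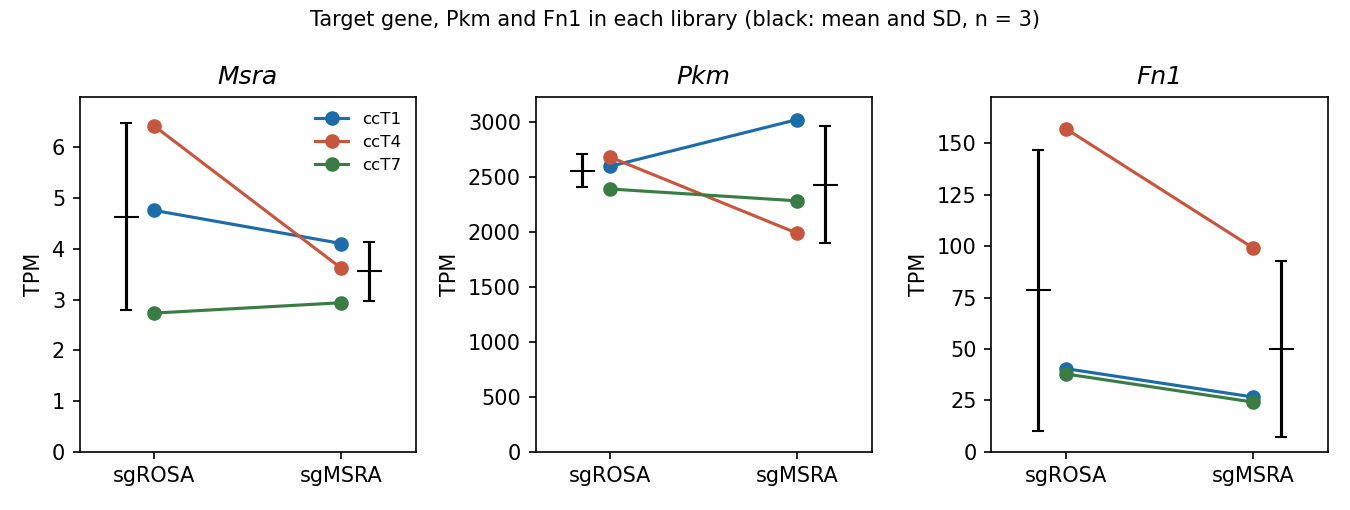
Expression of Msra, Pkm and Fn1 in TPM (vertical axes, from 0) in the sgROSA and sgMSRA libraries of each line; coloured lines join the 2 libraries of a line, and black marks give the mean and SD of the 3 libraries. Fn1 was lower with sgMSRA in 3 of 3 lines, whereas Msra was lower in ccT4, lower in ccT1 in TPM but not in log2 CPM (a ratio of 0.021), and slightly higher in ccT7.

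No gene passed an adjusted p of 0.05 between sgMSRA and sgROSA. Among 12788 genes tested with edgeR, 0 were higher and 0 lower in the comparison of the groups, and 0 were higher and 0 lower in the comparison within lines. At an unadjusted p under 0.05 there was 1 gene across groups, the unnamed model Gm44502, and 43 within lines. DESeq2 called 0 genes in both comparisons. Limma-voom called 0 genes across groups and 1 within lines, again Gm44502, whose counts were 0 and 14, 0 and 15, and 0 and 9 with sgROSA and sgMSRA in ccT1, ccT4 and ccT7. Gm44502 was singled out after its values were seen. In simulated data the comparison within lines recovered 96% of genes changed 4-fold and 44% of those changed 2-fold. The comparison across groups recovered 0% of either. The simulated genes were drawn independently, without the trend of the guide ratio with GC content described below. These shares therefore do not exclude 4-fold changes in the real data. The pseudogene Rps13-ps1, at log2 ratios of −1.99 in ccT1, −4.00 in ccT4 and −8.42 in ccT7, had an adjusted p of 0.379 within lines. Leaving out ccT1 changed the within-line count to 256 genes, 222 higher and 34 lower. That fit holds the pairs of ccT4 and ccT7 alone, and its spread was pooled over genes (13139 degrees of freedom). The count therefore does not rest on the spread of each gene between lines. Leaving out ccT4 gave 13 genes, and leaving out ccT7 gave 11.

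The 20 named genes with the smallest p within lines are given as values; each had an adjusted p of 1 in the comparison within lines. Fn1, the fibronectin gene (chromosome 1, 71585520 to 71653200), measured 40.4 and 26.7 TPM in ccT1, 157 and 99.2 TPM in ccT4, and 37.9 and 24.2 TPM in ccT7 with sgROSA and sgMSRA. Its log2 fold change was −0.59 ± 0.22 (SE), lower in 3 of 3 lines. The actin crosslinker gene Flnc had −0.60 ± 0.24 and was lower in 3 of 3 lines. The tight junction gene Cldn4 had −0.67 ± 0.29, and Thbs1, which encodes the matrix glycoprotein thrombospondin 1, had −0.46 ± 0.24, both lower in 3 of 3 lines. The gel-forming mucin gene Muc5ac had −0.74 ± 0.33 and was lower in 2 of 3 lines. Without ccT1, Fn1 (−0.70), Flnc (−0.74) and Cldn4 (−0.74) had adjusted p of 0.0454, 0.0357 and 0.0285. Sap25, Commd1b and Aldob passed as well. These p rest on a spread pooled over genes (13139 degrees of freedom), not on that of each gene. Without ccT4 Flnc was at −0.31, Cldn4 at −0.40 and Commd1b at 0.30, and none of them passed. Among genes of metabolism, Nanp, a phosphatase of sialic acid synthesis, had −1.50 ± 0.42 and was lower in 3 of 3 lines. It was −0.88 without ccT1 and passed only without the filter (adjusted p 0.0117). Aldob, the aldolase B gene, had 0.72 ± 0.34 and was higher in 3 of 3 lines. The glutathione transferase gene Gsta2 had 0.84 ± 0.44, higher in 2 of 3 lines. Prg2, which encodes eosinophil major basic protein, had 2.06 ± 0.62 at only 0.92 ± 0.77 TPM with sgROSA and 3.76 ± 4.002 TPM with sgMSRA (SD, n = 3). With all 6 libraries Prg2 passed with upper quartile scaling (adjusted p 0.0383) and without the filter (0.0026), and it passed without ccT1 (1.41, 0.0386) and without ccT7 (3.32, 0.00469), but not in the other alternatives. In the fits of all 6 libraries that passed, the fold changes stayed close to the main ones, at 2.08 and 2.05 for Prg2 and −1.51 for Nanp. Those calls rest on how the spread was estimated, and their p do not measure the spread of each gene alone. The placental hormone gene Prl2c2 had 0.44 ± 0.23. Lower values were found for Sap25 (−1.004), Tubgcp5 (−0.99), Neurl1a (−0.999), Tnk1 (−0.90), Zkscan7 (−0.78), the histone gene H3c14 (−0.75), Ace (−0.71) and Ism1 (−0.62), and higher ones for Commd1b (0.75) and Fam13a (0.75). Fam13a was 0.43 without ccT4. Without ccT1 Sap25 was −1.54, H3c14 −1.14, Zkscan7 −0.50 and Muc5ac −0.48, and without ccT7 Muc5ac was −1.11, Aldob 1.14 and Commd1b 1.16. The value of Tubgcp5 rested on ccT1, without which it was −0.11, and that of Neurl1a was −0.57 without ccT1 and −1.69 without ccT7. Commd1b, Prl2c2, Gsta2 and H3c14 belong to families of similar sequence, and the assignment of reads to them is uncertain. Of the 20 smallest p values before unnamed models and pseudogenes were set aside, 14 belonged to such models.

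Gene lists fixed in advance had small mean differences. The 25 tested genes of basement membrane and extracellular matrix had a mean log2 fold change of −0.20 within lines, with 22 below 0 and 3 above. With a preset correlation of 0.01 between genes the set test (camera) gave an adjusted p of 9.18e-09. With an estimated correlation the adjusted p was 0.896. Members with the smallest p were Thbs1 (−0.46), the anchoring collagen gene Col7a1 (−0.46), the laminin gene Lama3 (−0.56) and the fibulin gene Fbln2 (−0.42). The value of Lama3 comes from ccT1, with log2 ratios of −1.62 in ccT1, 0.0010 in ccT4 and −0.07 in ccT7. The mean of the matrix list was 0.21 in ccT1, −0.50 in ccT4 and −0.26 in ccT7. Within lines it was −0.031 without ccT4 and −0.077 without ccT7, and its call ended in both cases. Without ccT1 it was −0.36. The mesenchymal list of epithelial-mesenchymal transition (21 genes, 15 below 0) had a mean of −0.21, an adjusted p of 6.56e-05 with the preset and 0.896 with an estimated correlation. By line its mean was 0.26 in ccT1, −0.53 in ccT4 and −0.31 in ccT7. Its call ended without ccT4 (−0.0068) and without ccT7 (−0.17), and its mean was −0.39 without ccT1. Beside Fn1 its leading members were Col3a1 (−1.12), Fbn1 (−0.76) and Thy1 (−0.69), each under 1 TPM on average. The 5 tested fibroblast markers, all at low levels, had a mean of −0.51, with adjusted p of 5.56e-05 and 0.858. The call ended without ccT1 (−0.80) and without ccT4 (−0.12). By line their mean was 0.16 in ccT1, −1.36 in ccT4 and −0.35 in ccT7. None of the members of these 3 lists passed, also when adjusted over the list alone.

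Further lists with lower means concerned adhesion and signalling. Integrins and proteases had a mean of −0.15 (24 of 31 genes below 0), with Mmp10 at −1.50, Serpine1 at −0.30, Itgb4 at −0.25 and Itga3 at −0.25. Immediate early genes had −0.15 (15 of 18 below 0), with Fosb at −0.47 and Dusp1 at −0.35. Targets of YAP and TEAD had −0.12 (17 of 21 below 0), with Amotl2 at −0.31 and Ccn1 at −0.29. Targets of TGF-beta had −0.09 (17 of 21 below 0), with Ltbp2 at −0.40. The epithelial list had −0.08 (19 of 27 below 0), with Cldn4 at −0.67 but the transcription factor gene Grhl2 at 0.66, and genes of MYC and ribosome biogenesis had −0.07 (23 of 27 below 0). Their adjusted p with the preset correlation ran from 0.000261 to 0.0477, and with an estimated correlation from 0.858 to 0.896. Without ccT4 none of these 6 lists passed, with means, in the order given, of −0.055, 0.0094, −0.062, 0.063, 0.031 and 0.021. Without ccT1 the integrins (−0.12), YAP targets (−0.12) and MYC list (−0.094) missed the threshold, and without ccT7 the epithelial list (−0.074). In ccT1 itself the means of TGF-beta targets (0.13), the epithelial list (0.11) and immediate early genes (0.018) were above 0. Those of integrins and proteases (−0.20), YAP targets (−0.12) and the MYC list (−0.046) were below 0 there. The epithelial list passed only in the fit within lines (adjusted p of 0.409 across groups). Its call also ended with the length offset (mean −0.056, adjusted p 0.221) and with the GC and length offset (−0.044, 0.256), as did that of TGF-beta targets (−0.037, 0.354 and −0.071, 0.0595). The MYC list missed the threshold with the length offset (−0.071, adjusted p 0.0773).

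Redox and mitochondrial lists had higher means, 1 of them a sign of RNA quality. Targets of the oxidative stress factor NRF2 had 0.11 (24 of 30 genes above 0), with the glutathione transferase gene Gsta4 at 0.40 ± 0.24 (SE), the peroxiredoxin gene Prdx1 at 0.25 ± 0.22 and Cbr3 at 0.35 ± 0.31. Antioxidant enzymes had 0.09 (19 of 23 above 0), with Prdx4 at 0.29 and, against the rest, Gpx3 at −0.70. Nuclear genes of the tricarboxylic acid cycle and oxidative phosphorylation had 0.06 (32 of 40 above 0), and the 13 genes encoded by mitochondrial DNA had 0.14 (11 above 0), with mt-Co2 at 0.39. The latter list was written as a sign of RNA quality; its share of TPM was 7.02% and 5.73% in ccT1, 7.31% and 9.97% in ccT4 and 5.82% and 6.32% in ccT7 with sgROSA and sgMSRA. Their adjusted p with the preset correlation ran from 0.000232 to 0.025, and with an estimated correlation from 0.861 to 0.905. Without ccT1 the NRF2 list had a mean of −0.013, the antioxidant list −0.0017, the oxidative phosphorylation list −0.018 and the mitochondrially encoded list 0.18, and none of these 4 lists passed. The mitochondrially encoded list also missed the threshold without ccT4 (0.10, adjusted p 0.190), and oxidative phosphorylation without ccT7 (0.071, 0.0900). With the GC and length offset both calls ended (0.036 with an adjusted p of 0.138 for oxidative phosphorylation, 0.089 and 0.126 for the mitochondrially encoded list). The other methionine sulfoxide reductases and the thioredoxin system (12 genes) had a mean of 0.03 and an adjusted p of 0.672, and glycolysis had −0.03 and 0.738.

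In all, 13 of 37 lists passed within lines with the preset correlation, 4 higher and 9 lower, and 14 passed across groups, 6 higher and 8 lower. Pyruvate metabolism and cholesterol synthesis passed across groups alone (adjusted p 0.00802 and 0.0203, within lines 0.0608 and 0.0771) and the epithelial list within lines alone. With an estimated correlation, and by the directional rotation test (fry), 0 lists passed in either comparison. No member of any list passed over all genes or adjusted over the list alone within lines. The other 24 lists had adjusted p within lines from 0.0608 to 0.965. For 4 of these 24 the direction of the test differed from that of the mean or the median, namely heat shock, p53 targets, interferon response and leukocyte markers.

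**Figure D2:**
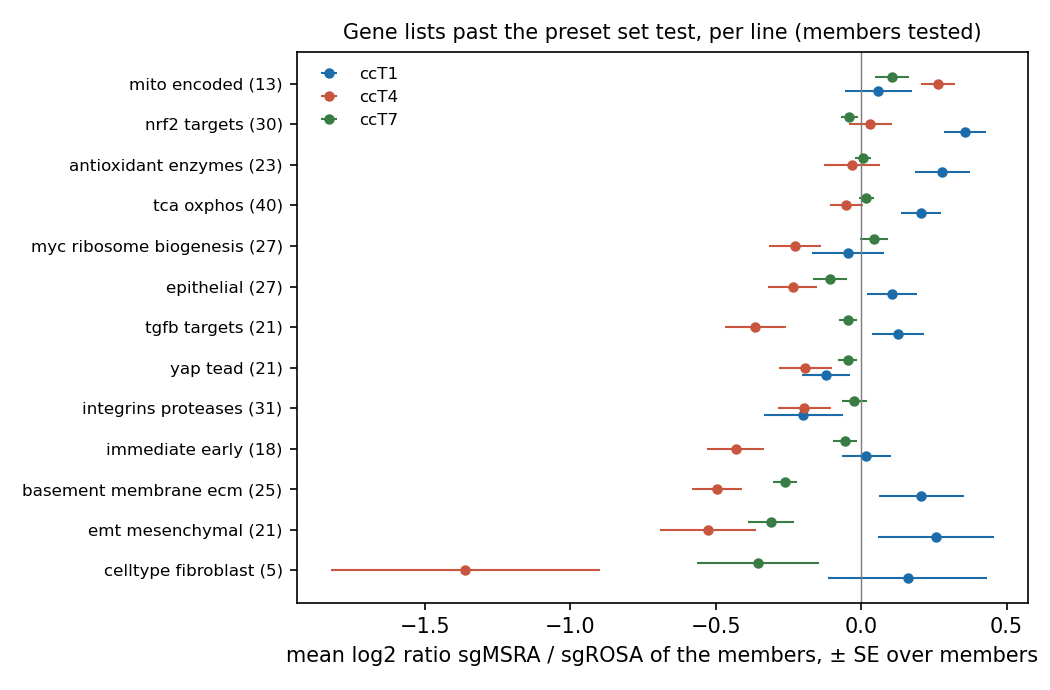
Mean log2 ratio of sgMSRA to sgROSA over the members of the 13 lists that passed the preset set test within lines (horizontal axis), by line; bars are the SE over members, and the number of tested members is in parentheses. The matrix list lay at 0.21 in ccT1, −0.50 in ccT4 and −0.26 in ccT7.

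The guide difference did not run the same way in the 3 lines. Across 12788 genes, which are not independent replicates, the log2 ratios of sgMSRA to sgROSA correlated at Pearson r = −0.49 and Spearman rho = −0.64 between ccT1 and ccT4, at −0.41 and −0.48 between ccT1 and ccT7, and at 0.26 and 0.48 between ccT4 and ccT7. The ratios of the 3 lines share no library, but each enters 2 of these correlations. Only 9.03% of genes had the same sign in all 3 lines, where independent signs would give 25%. The ratio followed the GC content of the transcripts. Among the 10702 genes above the expression minimum the Spearman correlation with GC content was 0.71 in ccT1, −0.78 in ccT4 and −0.64 in ccT7. In the fifth of genes with the lowest GC content the median log2 ratio was −0.79 in ccT1, 0.52 in ccT4 and 0.27 in ccT7, and in the fifth with the highest it was 0.37, −0.39 and −0.13. The 213 genes called higher when ccT1 was left out, at a mean CPM of at least 1, had a median GC content of 42.0%, against 50.8% over the genes tested. The 30 called lower, with Fn1, Flnc and Cldn4 among them, had a median of 55.0%.

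**Figure D3:**
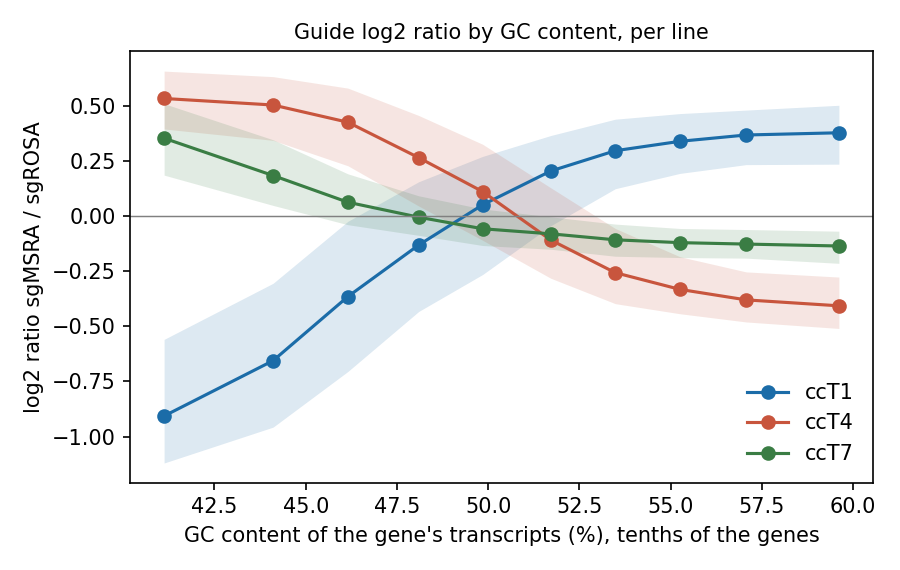
Log2 ratio of sgMSRA to sgROSA (vertical axis) against the GC content of the gene's transcripts in percent (horizontal axis), by line, for 10 equal groups of expressed genes by GC content; points are medians and bands the quartiles. The ratio rises with GC content in ccT1 and falls with it in ccT4 and ccT7.

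More genes differed among the lines than between the guides. With line and guide in one edgeR model, 1995 of 12788 genes (15.6%) differed among the 3 lines at an adjusted p under 0.05, and the first principal component, with 56.5% of the variance, placed both ccT4 libraries on one side and the other 4 on the opposite side. The genes furthest above the next line in ccT1 were Cldn18, a gastric tight junction gene at 401 and 361 TPM in the sgROSA and sgMSRA libraries and at no more than 1.09 TPM in the other lines, then Lrmp, Smarca1, Homer2, Cadps and Prex1. In ccT4 they were Evc2 (17.3 and 15.8 TPM) and its neighbour Evc (19.9 and 16.2 TPM), both genes of Hedgehog signalling at the cilium, then Blnk, the growth factor gene Gas6, Ptpru and Rassf9. In ccT7 they were Pcdhgb5, the gut surface antigen gene Gpa33, the stress ligand gene Ulbp1, the detoxifying enzyme genes Nqo1 and Gsta3, and Mb21d2. Nqo1 measured 15.7 and 14.9 TPM in ccT7 and at most 0.64 TPM elsewhere. Each line had 2 libraries, with different guides.

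Genes differing among lines were also counted per list, by a choice made after the data were seen, and no test compared these counts between lists. Of 24 genes of the classical pancreatic cancer subtype 15 differed among lines, as did 15 of 24 NF-kB and inflammation genes, 12 of 27 epithelial, 11 of 25 matrix, 10 of 21 mesenchymal and 7 of 10 basal subtype genes. So did 3 of 22 glycolysis, 3 of 22 p53 target, 1 of 27 MYC, 1 of 32 autophagy and 1 of 38 cell cycle genes and 0 of 40 tricarboxylic acid cycle and oxidative phosphorylation genes. Adjusted over the list alone, the counts were 21 classical, 19 NF-kB, 14 epithelial, 16 matrix, 14 mesenchymal, 7 basal, 0 cell cycle and 0 oxidative phosphorylation genes. Cldn4 stood at a log2 CPM of 5.32 in ccT4 against 0.58 in ccT1 and 1.84 in ccT7. The keratin gene Krt14 stood at 0.016 in ccT4 against 5.01 and 5.33. The N-cadherin gene Cdh2 stood at 0.13 in ccT7 against 6.75 in ccT1 and 6.45 in ccT4. Each line against the mean of the other two gave 11 of 111 set tests past an adjusted p of 0.05 with the preset correlation. The classical subtype was higher in ccT1 and lower in ccT4, the interferon response lower in ccT1, the mesenchymal, Wnt target and mitochondrially encoded lists higher in ccT4 and the NRF2 list lower there. In ccT7 the NRF2 and NF-kB lists were higher and the KRAS-MAPK and mitochondrially encoded lists lower. With an estimated correlation each of these had an adjusted p of 0.984.

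**Figure D4:**
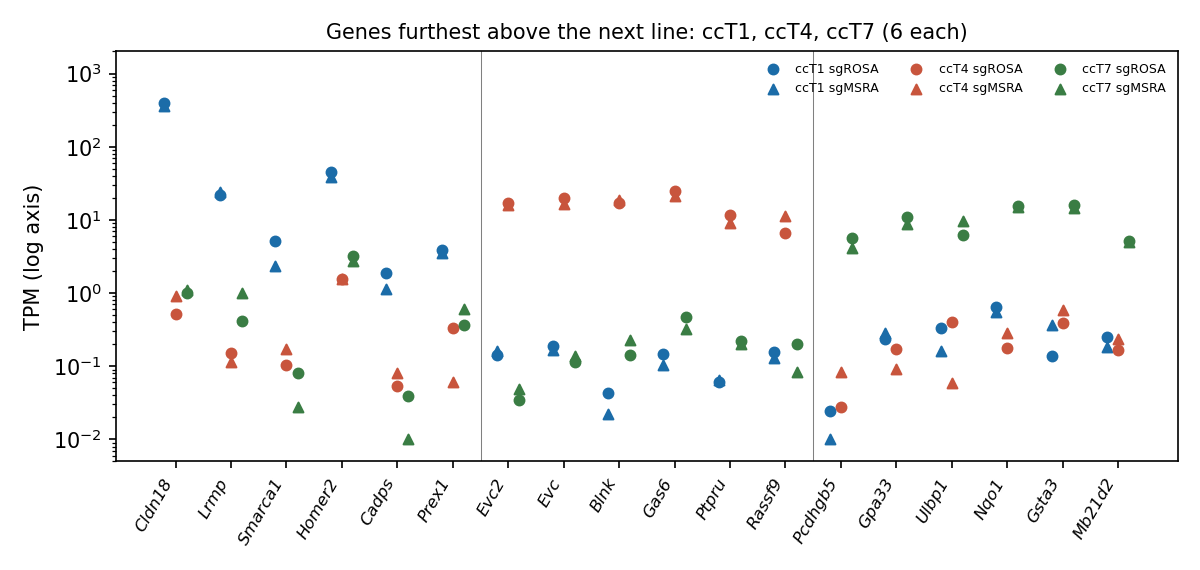
TPM (log axis) in each of the 6 libraries for the 6 genes furthest above the next line in ccT1 (left), ccT4 (middle) and ccT7 (right); values under 0.01 are drawn at 0.01. Circles are sgROSA and triangles sgMSRA libraries; the 2 libraries of the highest line lie close together for most genes.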

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

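Tests of GC content and length, of exchanged labels and of fibroblast RNA, and the split counts of genes within lines, were chosen after the results they bear on were seen. Results below were picked out because single pairs of libraries in different lines moved opposite ways. With 1 pair per line the difference was not tested. Groups of 3 were not examined for outliers.

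The log2 ratio of sgMSRA to sgROSA correlated with GC content at Spearman rho 0.71 in ccT1, −0.78 in ccT4 and −0.64 in ccT7, across genes that are not independent. Among single genes Prkn, which encodes the ubiquitin ligase parkin and was chosen after its values were seen, had 23 and 315 counts with sgROSA and sgMSRA in ccT1, a log2 ratio of 3.89, but 353 and 5 counts in ccT4, a log2 ratio of −5.77. In ccT7 it had 45 and 63 counts. Msra had a log2 ratio of −1.07 in ccT4 and 0.12 in ccT7, and Pkm had 0.46 in ccT1 and −0.54 in ccT4.

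The opposite direction of ccT1 and ccT4 across genes was weighed first. Unequal depth was argued against: after thinning all libraries to the lowest total the correlation was −0.51, against −0.49 before. GC content and length explained at least 55.4% of the variance of the ratio in both lines, in keeping with a part of the pattern. Over expressed genes the correlation was −0.70 before and −0.36 after the trend was removed (95% interval −0.41 to −0.31, with genes resampled as if independent). Whether the trend is the whole cannot be told from this. The values of a gene are medians over its annotated transcripts, so some of the trend may have stayed. Exchanged guide labels in ccT1 cannot be told apart from a library effect or from a response that differs between lines: with the trend removed, exchanging the ccT1 labels called 123 genes against 0 for the real labels and for exchanges in ccT4 or ccT7, and Msra itself does not separate the guides. A response particular to each line remains open and untested.

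The lower matrix and mesenchymal lists were weighed second. The GC and length trend, as measured over annotated transcripts, was argued against as the whole cause of their mean over the 3 lines. With it removed the matrix list kept a mean of −0.16, from −0.20, and an adjusted p of 3.54e-08 with the preset correlation. The mesenchymal list kept a mean of −0.19 and an adjusted p of 0.000299. The trend ran opposite ways in ccT1 and in ccT4 and ccT7, so it partly cancels in a mean over lines. The lists were not measured in single lines with the trend removed. Whether their lower means in ccT4 and ccT7 follow the trend therefore cannot be told. RNA from fibroblasts was argued against as the cause for the 26 members of both lists at 10 TPM or more: in ccT4 and ccT7 collagen I and III together were lower with sgMSRA by at most 0.12% of the summed difference of these members in CPM. For Fn1, which was lower in 3 of 3 lines, summed collagen I and III was lower in TPM by 6.07% of the difference in Fn1 in ccT1 and 2.87% in ccT4, and was higher in ccT7 (0.77 and 1.75 TPM). In CPM it was higher in ccT1 and lower by 0.28 in ccT7, so the direction of these low levels depends on the unit in both lines. These 2 tests were put in after a first one, on collagen levels, did not decide. For the 17 members below 10 TPM fibroblast RNA cannot be told apart from a change in the cells: the highest level of a collagen I or III transcript was 1.54 TPM, in the sgMSRA library of ccT7, and the fibroblast list was also lower. Also open is that genes of a list vary together, since the call is lost with an estimated correlation, and that it rests on ccT4 and ccT7, without which the mean was −0.031 and −0.077.

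The 6 libraries allow 10 splits, too few for a share under 0.05. Across groups the real split called 0 genes and the highest of the others 0. With 0 real calls all 10 splits gave as many by definition, so the gene counts cannot weigh chance. Within lines the real split called 0 genes and the highest other 2694, again with all 10 splits as high by definition. That highest split exchanges the guides of ccT1 alone, and so many calls point to a structure of the samples: they restate that ccT1 runs opposite to ccT4 and ccT7, and leave open whether a response particular to a line, a library effect or exchanged labels lies behind it. Among the 4 splits that keep 1 library of each line in each group, exchanging ccT4 called 12 genes and exchanging ccT7 called 1. For the lists, the real split gave 14 across groups and the highest other 9, and within lines 13 and 12, so 1 split, the real one, gave as many in each case.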

How the results depend on the processing

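The alternative with the GC and length offset was added after the data were seen; the others were planned. Across groups 0 genes were called under every alternative run, the line block included (0). Within lines the count was 0 under RLE, the stricter filter, the length offset, DESeq2, each limma fit on TPM, an adjusted p of 0.1, the GC and length offset and no block (0), but 5 with upper quartile scaling, 24 without the filter, 1 with limma-voom, and 11 to 256 when 1 line was left out. Lists past the threshold fell to 0 with an estimated correlation and 0 with fry in both comparisons, and without 1 line numbered 7 to 17 across groups and 6 to 11 within lines. With the block 13 lists passed in place of 14: pyruvate metabolism and cholesterol synthesis missed the threshold and the epithelial list passed it. The Msra log2 fold change was −0.31 with the block and −0.67 to 0.076 without 1 line.

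Genes differing among lines numbered 3262 without the filter and 3562 with the GC and length offset. The correlation of line effects between ccT1 and ccT4 was −0.59 on log2(TPM + 1), −0.61 with the stricter filter, −0.41 at a prior count of 0.5 and −0.19 with the GC and length offset. Between ccT1 and ccT7 it was −0.49, −0.53, −0.35 and −0.21, and between ccT4 and ccT7 0.38, 0.39, 0.20 and 0.053, in the same order. The cause of these shifts was not tested.

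Among the named genes and the lists called in either comparison, signs turned only when 1 line was left out, so fewer samples are involved. Means near 0 of lists not called also turned with all libraries. That of cell cycle genes within lines went from 0.012 to −0.0082 with the GC and length offset. Within lines Msra ranged from −0.53 to 0.093 and Pkm from −0.30 to 0.22. List means ranged from −0.0017 to 0.18 for antioxidant enzymes, −0.013 to 0.19 for NRF2 targets, −0.018 to 0.13 for the tricarboxylic acid cycle and oxidative phosphorylation, −0.0047 to 0.13 for pyruvate metabolism, −0.047 to 0.13 for cholesterol synthesis, −0.18 to 0.031 for the epithelial list, −0.22 to 0.063 for TGF-beta targets, −0.25 to 0.0094 for immediate early genes and −0.14 to 0.021 for MYC and ribosome biogenesis. Of the other values of single genes 307 kept their direction and side of the threshold and 11 passed it. Of those of single lists 98 kept both, 49 lost the threshold and 8 passed it. Depth limits only genes with few counts.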

Other observations

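Vimentin was abundant beside epithelial keratins in every library. Its gene Vim, which encodes a filament protein of mesenchymal cells, measured 2186 to 2502 TPM, beside the epithelial keratins Krt8 at 3504 to 4620 TPM and Krt19 at 2466 to 3918 TPM and the E-cadherin gene Cdh1 at 161 to 310 TPM. The mesenchymal gene Cdh2 by contrast measured 0.44 and 0.31 TPM in ccT7. Among the other methionine sulfoxide reductases, Msrb1 measured 41.9 to 59.6 TPM, Msrb2 4.87 to 15.04 TPM and Msrb3 0.73 to 1.23 TPM. No test was applied to these levels.

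Rps13-ps1, a processed pseudogene of the ribosomal protein gene Rps13, had fewer counts with sgMSRA in 3 of 3 lines: 1368 and 285 in ccT1, 326 and 19 in ccT4, and 729 and 0 in ccT7. Its adjusted p within lines was 0.379. It was 5.47e-18 with upper quartile scaling, 2.37e-24 without the filter, 2.92e-70 without ccT1, 4.63e-11 without ccT4 and 0.00414 without ccT7. In the other alternatives it did not pass. Its log2 fold change was −4.04 with upper quartile scaling and −3.73 with the GC and length offset, where it did not pass. The fit without ccT1 holds the pairs of ccT4 and ccT7 alone. Its spread was pooled over genes (13139 degrees of freedom), so that p does not measure the spread of Rps13-ps1 itself. The same limit holds for the other p under 0.05 given here. With 2 residual degrees of freedom or fewer, and log2 ratios from −1.99 to −8.42 between lines, they cannot rest on the spread of Rps13-ps1 alone. The parent Rps13 had 16890 and 18847 counts in ccT1, 13452 and 9316 in ccT4, and 12229 and 10095 in ccT7. Reads shared with the parent cannot be separated in these files, and the pseudogene was chosen after its values were seen.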
